A study of Sus scrofa with 18 samples.

How the data were processed

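Total RNA from piglet retina was hybridised to Affymetrix pig arrays, 18 arrays from 18 male piglets of a Landrace and Large White cross, 9 per diet group, as the labels describe. Groups and replicate numbers were taken from the sample titles, and each sample was 1 array. The labels state that the piglets were placed in the groups at random. They name no litter, array batch or scan date, so none was tested.

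The deposited table held 1 log2 value per probe set and array. Per the submitters' processing notes, Affymetrix Expression Console and RMA were used. RMA in general corrects background, normalizes quantiles between arrays and summarises the probes of a set by a robust fit; which settings were used is not given in the sources used here. The log2 scale follows from the deposited values, the lowest of which was 0.146. RMA values carry no detection call, shrink differences of dim probe sets and place all arrays on 1 distribution, so that a change shared by most genes cannot be seen. All value columns were mapped to a sample by name.

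From these values, 124 control probe sets were left out, then the 30% of the remaining probe sets with the lowest mean over all 18 arrays (7200), which left 16799. Gene symbols came from the platform annotation. In the file 10099 probe sets had 1 gene symbol, 198 had several and 13826 had none in that annotation; probe sets with none are unnamed here, and none was named from a probe set with several. For 9989 named probe sets the gene identifier was found in a RefSeq gene table, and 0 symbols changed. A gene was represented by its tested probe set with the highest mean. Of the 5710 genes, 1562 had more than 1 tested probe set. No coordinates are given, because the sources used here name no build for the array.

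Diets were compared, sialyllactose minus control, with limma (lmFit and eBayes without trend) on all 18 arrays without covariates, with Benjamini-Hochberg adjustment over the tested probe sets and a threshold of 0.05. Named genes carry their group mean ± SD, and fold is 2 to the power of the difference of mean log2 values. Gene lists were tested with camera at a preset correlation of 0.01 on lists with at least 5 tested genes, again with an estimated correlation, and with fry, which asks whether a list's genes move on balance one way. Of 37 lists fixed before the data were examined, 27 had at least 5 tested genes. A list score is the mean over the list's genes of each array's deviation from the gene's mean over 18 arrays, tested by an exact permutation of 48620 label splits. The share of variance between diets was the between-group share of squared Euclidean distances, with 100000 label permutations. The spread between piglets was each array's distance to its own group mean, tested by the same exact permutation. R 4.3.3 and limma 3.58.1 were used.

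The genes named were set by a rule fixed before the data were examined. It took all genes at an adjusted p under 0.05, filled to 12 per direction by the smallest unadjusted p, then 25 key genes of the retina and of sialic acid metabolism where measured, up to 4 members of a list that passed camera and up to 2 of other lists. Which of the other lists have members named was chosen after their values were seen. Of the 25 key genes, 12 had a named probe set, 11 were tested and 1, CMAH, was dim. The other key genes had no named probe set and were not analysed here. Of the 72 genes named by the rule, 15 had more than 1 tested probe set, and in 7 of these the probe sets differed in sign.

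The limma step was tested on simulated data for sialyllactose minus control, with 200 of 16799 probe sets changed. It recovered 30.5% of them at a change of 1.19-fold, 87.0% at 1.41-fold and 100% at 2-fold, so a few probe sets with differences near 1.2-fold would often be missed with 9 arrays per group. The alternatives tried were no filter on dim probe sets, a filter of 50%, centring each array on its median, quantile normalization over the tested probe sets, the replicate number as a block, the first principal component of the residuals as a covariate, array quality weights, an intensity trend with a robust prior, exact rank-sum tests, an adjusted p threshold of 0.1, gene means over probe sets, camera with estimated correlation, fry, and leaving out each array in turn. The interferon list score as a covariate was added after the data were seen.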

Results

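Gene expression was measured in the retinas of 18 male piglets at postnatal day 38 with Affymetrix pig arrays, 1 array per piglet. The labels place 9 piglets on milk replacer alone (control) and 9 on milk replacer with added sialyllactose, a milk sugar made of lactose joined to sialic acid, from an enrolment age of 3 days. Sialic acid is a building block of gangliosides and of the polysialic acid carried by neural adhesion molecules, and the series title names retinal development and vision as its subject. The file held 24123 probe sets with log2 values from 0.146 upward. After control and dim probe sets were left out, 16799 probe sets were tested, of which 7792 had exactly 1 gene symbol, representing 5710 genes. Correlations between arrays over the tested probe sets lay between 0.981 and 0.992, and no pair of arrays held identical values. The number of arrays limits the precision of every value below.

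The first comparison asked which genes differed in level between the diets. Genes with the smallest p included BUB3, a mitotic checkpoint gene, at 7.15 ± 0.26 in control and 6.84 ± 0.07 with sialyllactose (log2, mean ± SD, n = 9 each), LFNG, which modifies Notch receptors (5.27 ± 0.13 against 4.98 ± 0.21), and PSMC1, a proteasome subunit (6.30 ± 0.11 against 6.08 ± 0.11). In each of these 3 genes, all 9 sialyllactose piglets lay below the control median. On the higher side, SCG2, the precursor of the neuropeptide secretoneurin, was measured at 8.52 ± 0.28 with sialyllactose against 8.21 ± 0.12, and AHR, the aryl hydrocarbon receptor, at 4.51 ± 0.10 against 4.34 ± 0.09. None of these differences passed the test across all probe sets, and the folds were small.

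The 12 genes with the smallest p and higher means with sialyllactose were C4BPA, ARAF, CDC42EP2, AHR, LOC396794, MCM2, MCRS1, CDR2L, FOXP3, PRSS2, MCT7 and SCG2, with folds of 1.12 to 1.23. C4BPA encodes a complement regulator, ARAF a kinase, MCM2 a subunit of the DNA replication helicase and FOXP3 a transcription factor of regulatory T cells. Of these 12 genes, 10 had mean levels below the median of the tested probe sets, FOXP3 among them at 1.56 ± 0.13 in control and 1.76 ± 0.12 with sialyllactose. The 12 lower genes were PSMC1, LFNG, BUB3, ANXA5, RNF214, TMEM263, LOC100620869, RHOJ, PPP1CA, TMEM158, LAMC1 and MT3, with folds of 0.809 to 0.885. Among them LAMC1 encodes a laminin chain of basement membranes and MT3 a brain metallothionein, and MT3 was measured at 6.80 ± 0.16 in control and 6.52 ± 0.21 with sialyllactose. The limma adjusted p was 0.691 for all 24 genes.

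In limma, 0 of the 16799 probe sets had an adjusted p under 0.05, and the lowest adjusted p was 0.691. At an unadjusted p under 0.05 there were 1059 probe sets, 494 higher and 565 lower, where 840 would fall by chance. At an unadjusted p under 0.01 there were 219, 106 higher and 113 lower, where 168 would fall by chance, and exact rank-sum tests likewise gave 0 probe sets after adjustment and 202 at an unadjusted p under 0.01. With each array centred on its median, the numbers at an unadjusted p under 0.01 were 179 higher and 70 lower, and with a 50% filter on dim probe sets 45 higher and 94 lower, so the balance of directions depended on scaling and on the filter. The median absolute difference was 0.05 on the log2 scale. The 95% interval of the difference lay within 1.5-fold in either direction for 98.7% of the probe sets and within 2-fold for 99.8%.

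The second comparison asked whether genes that make, attach or remove sialic acid differed between the diets. The key genes of sialic acid synthesis had closely similar levels. GNE, the rate-limiting enzyme, was measured at 4.69 ± 0.16 in control and 4.59 ± 0.14 with sialyllactose (log2, n = 9 each), NANS, which forms sialic acid phosphate, at 5.59 ± 0.13 and 5.54 ± 0.15, and CMAS, which activates sialic acid for transfer, at 6.04 ± 0.14 and 5.97 ± 0.07. Their differences were -0.09 (95% interval -0.24 to 0.05), -0.05 (-0.19 to 0.08) and -0.06 (-0.18 to 0.05). The NANS difference was -0.02 without control replicate 2, -0.03 without sialyllactose replicate 2 or 4 and -0.09 without sialyllactose replicate 7, that of GNE was -0.06 without sialyllactose replicate 6 and that of CMAS -0.04 without control replicate 8. NEU1, the lysosomal sialidase, differed by -0.001 (-0.12 to 0.11), a direction that turned under both other scalings and in 9 of the 18 fits without 1 array. In the sialic acid metabolism list, 3 of 13 tested genes had higher and 10 lower means with sialyllactose and none passed the test (camera adjusted p = 0.552, median difference -0.03). Without single arrays the median difference ran from -0.06 (without sialyllactose replicate 1) to -0.01 (without control replicate 2). The smallest p in it belonged to PGM3, an enzyme of the hexosamine pathway, at 5.03 ± 0.12 and 4.89 ± 0.09, followed by GNPNAT1 of the same pathway at 5.41 ± 0.12 and 5.51 ± 0.08.

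Of 6 sialyltransferases, 4 were higher and 2 lower (camera adjusted p = 0.552). ST6GAL1 was measured at 4.34 ± 0.11 in control and 4.44 ± 0.18 with sialyllactose, ST3GAL4 at 4.28 ± 0.25 and 4.34 ± 0.14, and ST8SIA4, a polysialyltransferase, at 2.54 ± 0.29 and 2.51 ± 0.09. The ST8SIA4 difference of -0.03 turned without control replicate 3 (0.004), 6 (0.003) or 9 (0.01). Of 9 tested genes in the list of ganglioside synthesis and breakdown, 5 were higher and 4 lower (camera adjusted p = 0.552), with ARSA, the lysosomal arylsulfatase, at 3.08 ± 0.14 and 3.22 ± 0.12 and GM2A, the GM2 activator, at 3.33 ± 0.14 and 3.43 ± 0.29. The others were PSAP, ASAH1, GLB1, GLA, SMPD1, B4GALT5 and HEXA, so the list mostly covered breakdown of sphingolipids, not of gangliosides alone. The key genes ST3GAL5 and ST8SIA1 had no named probe set, and ganglioside synthesis was hardly measured. NCAM1, the main carrier of polysialic acid, differed by -0.04 (95% interval -0.15 to 0.07) in its brightest probe set, and 2 of its 4 tested probe sets had that sign. That difference was -0.02 without control replicate 2 or 9 or sialyllactose replicate 5. Among the 4 tested genes of neural adhesion and sugar binding, LGALS1, a galectin, was measured at 8.05 ± 0.29 in control and 7.82 ± 0.18 with sialyllactose and CADM1 at 4.22 ± 0.25 and 4.33 ± 0.14. CMAH, which converts one form of sialic acid into another, lay under the level filter with a mean of 0.956. BDNF, a neurotrophin, was measured near the floor at 1.99 ± 0.13 and 2.16 ± 0.11, and NTRK3, a neurotrophin receptor, at 2.87 ± 0.27 and 2.63 ± 0.20. Of the 13 tested neurotrophic factors and receptors, 4 were higher and 9 lower (camera adjusted p = 0.992). None of these named genes passed the limma test across all probe sets.

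The third comparison asked whether the retina's cell types or processes, as fixed gene lists, differed between the diets. Of 27 lists with at least 5 tested genes, 1 passed camera, the ribosomal proteins, in which 51 of 55 tested genes had lower means with sialyllactose and 4 had higher means. The list's median difference was -0.04 on the log2 scale (camera adjusted p = 0.000195, and adjusted p = 0.722 with a correlation estimated at 0.377). The members with the smallest p were RPS15 at 8.32 ± 0.09 in control and 8.22 ± 0.07 with sialyllactose, RPS9 at 7.71 ± 0.13 and 7.60 ± 0.07, RPL27 at 8.46 ± 0.07 and 8.38 ± 0.06, and RPL5 at 8.92 ± 0.05 and 8.84 ± 0.08 (log2, n = 9 each). Each gene was taken at its brightest probe set, and the probe sets of a gene could differ in sign. Of 3 tested probe sets each, that sign was held by 2 in RPL27, 1 in RPL23, 1 in RPL12 and 3 in RPS18. No single member passed the limma test. The call rested on camera's preset correlation of 0.01. It was also lost when each gene was the mean of its probe sets (adjusted p = 0.213), although the median difference stayed at -0.04, and did not pass in fry (unadjusted p = 0.105). With arrays centred on their medians or quantile normalized again, the list passed with smaller median differences, -0.02 and -0.03. No list call held with an estimated correlation.

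**Figure D1:**
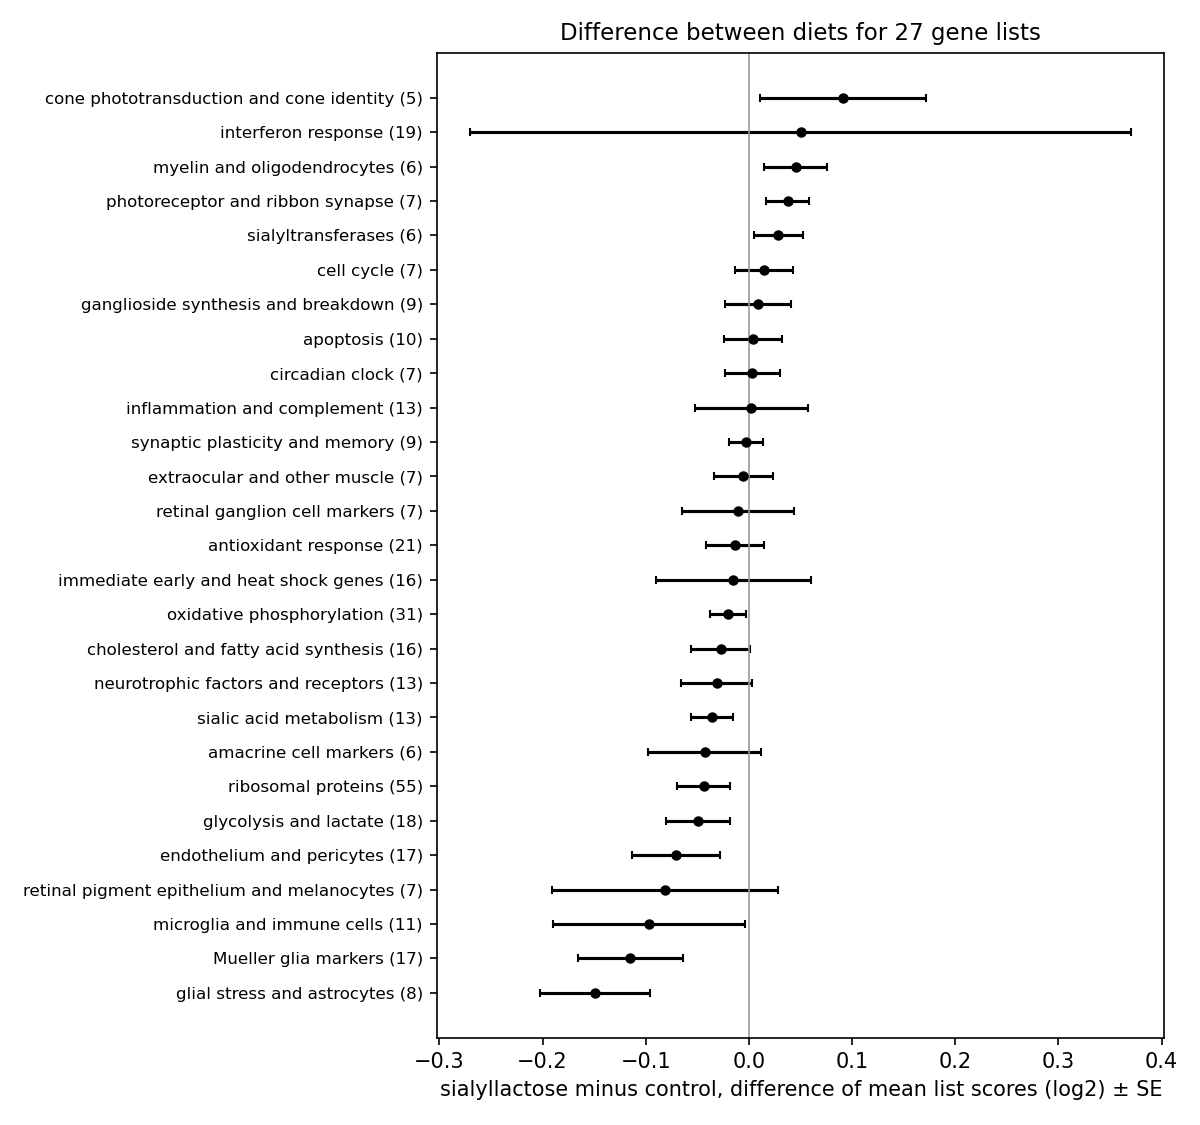
Difference of mean list scores between diets for each of the 27 gene lists, in log2 units on the horizontal axis, where points are sialyllactose minus control, bars are the standard error from 9 piglets per diet and brackets hold the number of tested genes. The glial lists lie farthest below 0, at -0.15 and -0.11, and the interferon list has the widest bar, with a standard error of 0.32.

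Glial genes were on the lower side with sialyllactose without passing the adjusted test. VIM, the intermediate filament of Mueller glia, was measured at 8.78 ± 0.24 in control and 8.51 ± 0.21 with sialyllactose, and 8 of 9 sialyllactose piglets lay below the control median. CD9 was measured at 5.47 ± 0.30 and 5.23 ± 0.25, while GLUL, the glutamine synthetase of Mueller glia, was at 10.6 ± 0.22 and 10.5 ± 0.31 and RLBP1, a retinoid carrier of the same cells, at 8.90 ± 0.22 and 8.81 ± 0.15 (log2, n = 9 each). Without control replicate 2 the difference of GLUL was -0.06 instead of -0.11 and that of RLBP1 -0.04 instead of -0.09, and without sialyllactose replicate 8 that of GLUL was -0.07. Of 17 Mueller glia markers 13 were lower and 4 higher, with a median difference of -0.11 (camera adjusted p = 0.201, and adjusted p = 0.722 with an estimated correlation). Without control replicate 8 the list passed camera with the preset correlation (adjusted p = 0.0224, median difference -0.15).

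GFAP, a filament protein of astrocytes and stressed Mueller glia, was measured at 5.69 ± 0.38 in control and 5.28 ± 0.23 with sialyllactose in its brightest probe set, a difference of -0.41 (95% interval -0.69 to -0.13), and all 9 sialyllactose piglets lay below the control median. Its other 3 tested probe sets were dimmer and differed by 0.12, -0.02 and 0.25 (95% interval of the last 0.05 to 0.45), so the probe sets of the gene disagreed in sign. Over all probe sets GFAP did not pass (limma adjusted p = 0.691), while adjusted over the list alone it did (0.0461). CEBPD, a transcription factor of the stress response, was measured near the floor at 2.21 ± 0.53 and 1.86 ± 0.28, and its difference of -0.35 was -0.20 without control replicate 3. In the list of glial stress and astrocyte genes, 7 of 8 were lower and 1 higher (camera adjusted p = 0.226, and adjusted p = 0.722 with an estimated correlation). The mean score of this list differed by -0.15 ± 0.05 (SE), with a two-sided exact permutation p = 0.0116 and an adjusted p of 0.313 over the 27 lists. Over the lists alone, 2 genes passed in all, GFAP and the cell cycle gene MCM2 (0.0182), against 0 over all probe sets. The adjustment within a list was repeated for each of the 27 lists, so some genes could pass by chance.

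**Figure D2:**
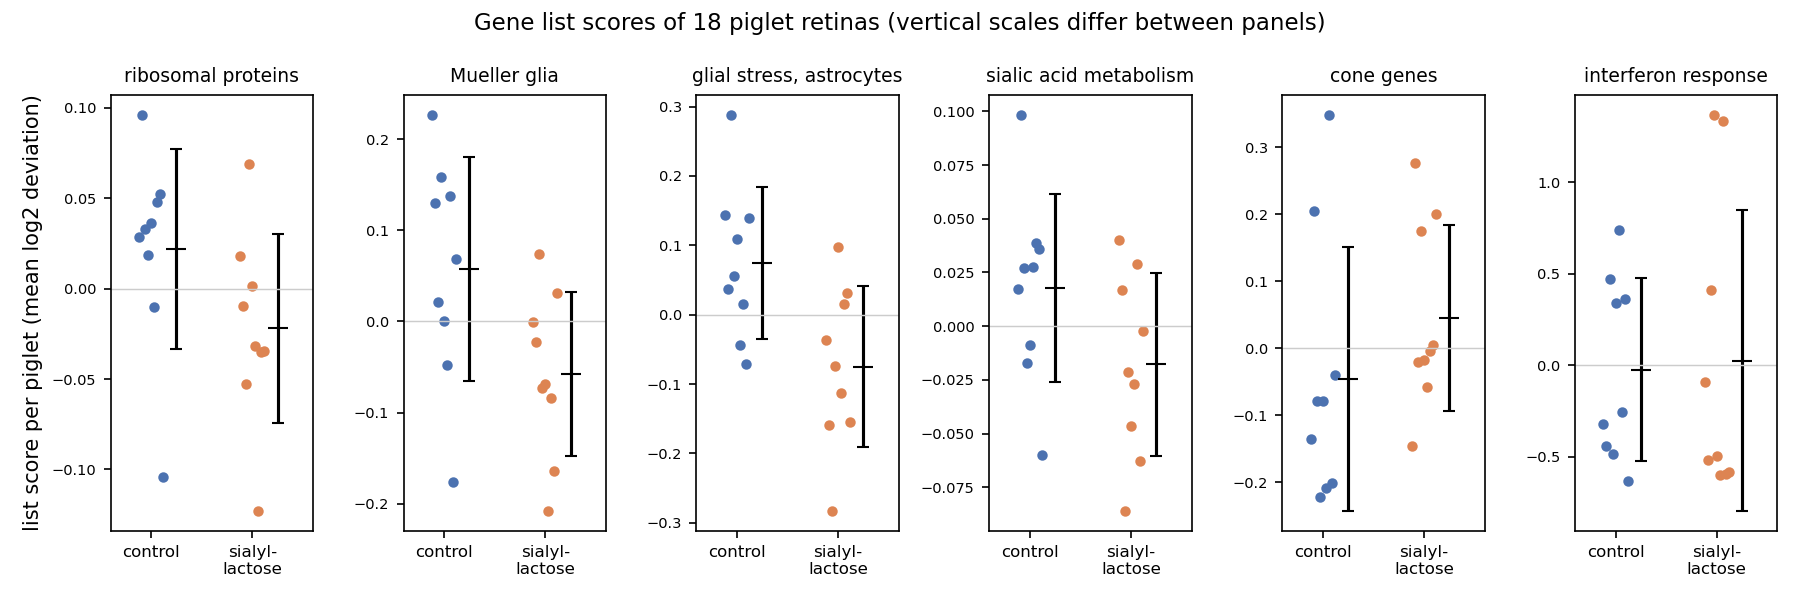
List score of each piglet (mean log2 deviation of the list's genes from their means over 18 arrays, vertical axis) for 6 gene lists by diet, where points are piglets, black marks the mean and bars the SD of 9 piglets, and each panel has its own scale. The diets overlap in every panel, and interferon scores run from -0.63 to 1.37.

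Cone and synapse genes mostly had higher means with sialyllactose, without either list passing the adjusted test. All 5 tested cone genes had higher means with sialyllactose, among them GRK7, a cone opsin kinase, at 3.52 ± 0.30 in control and 3.70 ± 0.19, ARR3, cone arrestin, at 9.57 ± 0.34 and 9.69 ± 0.21, and OPN1SW, the short-wave cone opsin, at 5.14 ± 0.46 and 5.20 ± 0.29 (log2, n = 9 each). The cone list had a median difference of 0.07 (camera adjusted p = 0.268, and adjusted p = 0.722 with an estimated correlation). Without control replicate 7 it passed camera with the preset correlation (adjusted p = 0.0398, median difference 0.17). Its median difference was 0.04 without control replicate 6 or sialyllactose replicate 4 and 0.13 without sialyllactose replicate 1, and the OPN1SW difference of 0.06 was -0.002 without control replicate 5. Of 7 tested genes in the photoreceptor and ribbon synapse list 6 were higher and 1 lower (camera adjusted p = 0.226), with SNAP25 at 9.86 ± 0.18 and 9.96 ± 0.05 and VAMP2, also part of the vesicle fusion machinery, at 5.78 ± 0.12 and 5.83 ± 0.08. NSF, SYT1, CTBP2, SYN1 and SYN2 made up the rest, so the list mostly covered general synapse genes. The sign of the brightest probe set was held by 2 of 3 in NSF, 1 of 2 in SYT1 and 1 of 2 in CTBP2. Of the rod genes 2 were tested, SAG, rod arrestin, at 10.7 ± 0.10 and 10.6 ± 0.17, and CNGA1, a rod channel subunit, at 3.19 ± 0.45 and 3.47 ± 0.21. In the visual cycle 2 of 4 tested genes were higher, with RBP4 at 2.82 ± 0.17 and 2.98 ± 0.21.

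Other cell types did not separate the diets. The amacrine cell list (6 tested genes) had a camera adjusted p of 0.789 and the ganglion cell list (7 genes) one of 0.992. Of 11 microglia and immune genes 8 were lower (camera adjusted p = 0.553), with LAPTM5 at 2.81 ± 0.43 in control and 2.43 ± 0.31 with sialyllactose and CD14 differing by 0.13 (95% interval -0.01 to 0.26; 0.08 without control replicate 6). Of 17 endothelial and pericyte genes 12 were lower (camera adjusted p = 0.359), with TEK, the angiopoietin receptor, at 1.86 ± 0.14 and 1.62 ± 0.17 and PECAM1 at 3.71 ± 0.16 and 3.56 ± 0.14. Markers of tissue that dissection can bring along were also tested. Of 7 pigment epithelium genes 5 were lower (camera adjusted p = 0.552), with BEST1 at 4.54 ± 0.26 and 4.27 ± 0.21 and OCA2 at 1.88 ± 0.23 and 1.72 ± 0.18. TEK, CD14 and OCA2 lay near the floor, at percentiles 7.96, 3.03 and 9.69 of the tested probe sets by mean level. The muscle list had an adjusted p of 0.992 and the myelin list one of 0.501. The 10 lists with fewer than 5 tested genes (rod, visual cycle, glutamate and GABA receptors, bipolar, horizontal, lens, cornea and ciliary epithelium, red blood cells, neural adhesion, retinal transcription factors) held 24 tested entries, 10 higher and 14 lower, of which 2 had an unadjusted p under 0.05.

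Genes of energy use and stress gave no passing list. Of 18 glycolysis genes 14 were lower (camera adjusted p = 0.281), with ENO1, an enolase, at 9.28 ± 0.16 in control and 9.07 ± 0.18 with sialyllactose and PFKP, a phosphofructokinase, at 5.75 ± 0.23 and 5.53 ± 0.19. Of 31 oxidative phosphorylation genes 23 were lower (adjusted p = 0.476). Of 16 cholesterol and fatty acid synthesis genes 11 were lower (adjusted p = 0.552), with SCD, a fatty acid desaturase, at 5.47 ± 0.16 and 5.25 ± 0.17 and ELOVL6, an elongase, at 5.57 ± 0.24 and 5.36 ± 0.37. Among immediate early and heat shock genes (16 tested, adjusted p = 0.992), CRYAB, a small heat shock protein, was measured at 6.39 ± 0.50 and 5.95 ± 0.24 with all 9 sialyllactose piglets below the control median, and DUSP1 at 5.69 ± 0.22 and 5.57 ± 0.18. The DUSP1 difference of -0.12 was -0.05 without control replicate 3. The camera adjusted p was 0.501 for the antioxidant list, 0.552 for the circadian clock and for inflammation and complement, 0.763 for apoptosis, 0.789 for the cell cycle and 0.992 for synaptic plasticity. In 7 lists (ganglion cells, muscle, myelin, synaptic plasticity, cell cycle, apoptosis, immediate early and heat shock) the median, the mean and the direction given by camera did not share a sign. At an unadjusted p under 0.05, camera gave 5 lists with the preset and 1 with estimated correlations, and fry gave 1.

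The fourth comparison asked how far the diets stood apart and how much piglets on the same diet differed. Interferon response genes differed far more between piglets than between diets. ISG15, an interferon-induced ubiquitin-like protein, ranged from 2.83 to 6.47 in control and from 2.85 to 8.02 with sialyllactose, RSAD2 from 1.28 to 4.47 and from 1.29 to 5.63, and MX1, an antiviral GTPase, from 4.63 to 6.37 and from 4.56 to 7.77. These 3 genes were chosen after their values were seen. The diet means of ISG15 were 4.61 ± 1.35 in control and 4.61 ± 2.05 with sialyllactose (n = 9 each). Of the 50 genes with the largest SD within diets, 10 belonged to the 19 tested interferon genes (Fisher's exact test, one-sided, p = 8.89e-17), a test that treats genes as independent. The interferon list score differed between the diets by 0.05 ± 0.32 (SE; two-sided exact permutation p = 0.883), and the list did not pass camera (adjusted p = 0.281). Its members with the smallest diet p were IRF7 at 2.28 ± 0.20 in control and 2.46 ± 0.33 with sialyllactose and PSMB8 at 1.54 ± 0.23 and 1.72 ± 0.37, whose difference of 0.18 was 0.06 without sialyllactose replicate 4. PSMB8 lay near the floor, at percentile 4.88 of the tested probe sets by mean level.

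**Figure D3:**
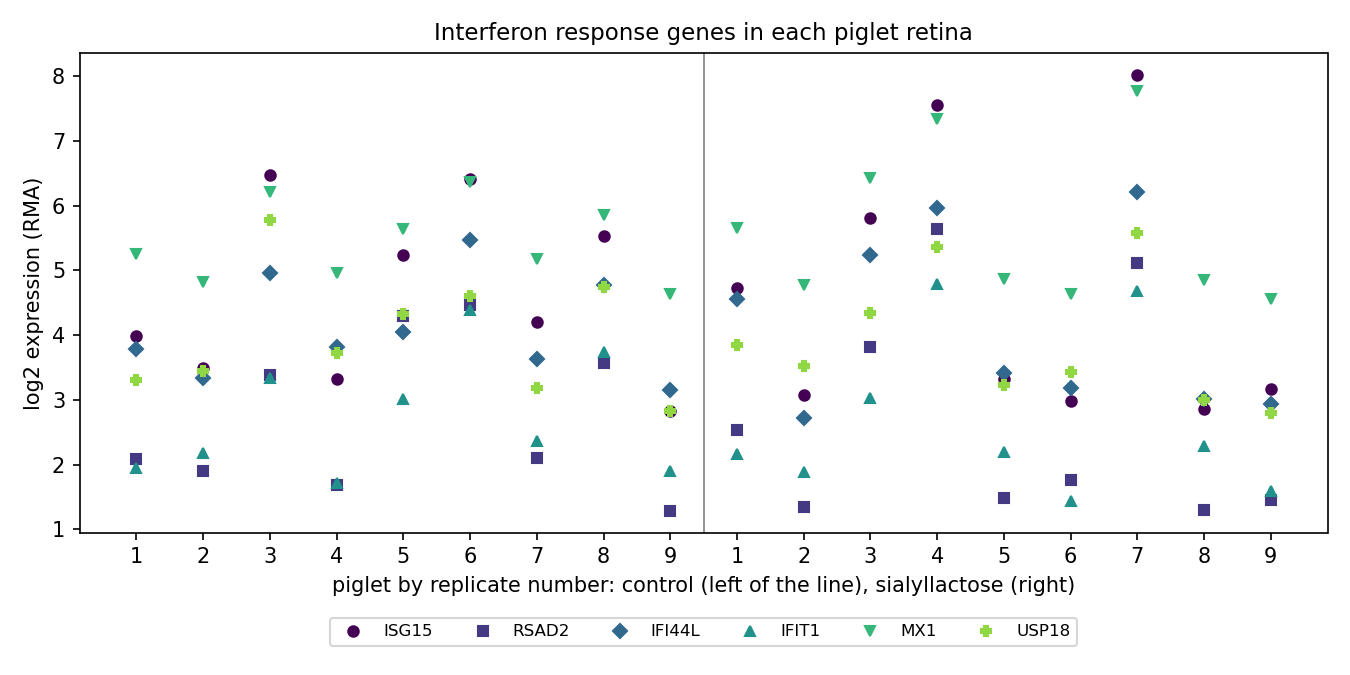
Log2 expression (vertical axis) of 6 interferon response genes in each of the 18 piglets, by replicate number within diet (horizontal axis, control left of the line). Each symbol is 1 gene on 1 array, and the genes move together, with ISG15 from 2.83 to 8.02 over both diets.

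Diet accounted for 6.03% of the variance between arrays over the tested probe sets (permutation p = 0.350), against 5.88% by chance. The mean Euclidean distance of an array to its own group mean was 24.1 ± 3.44 (SD) in control and 22.2 ± 0.98 with sialyllactose, a difference of -1.92 (two-sided exact permutation p = 0.0780). Control replicate 2 had the largest distance, 32.6, and without it the difference was -0.49 (exact p = 0.424). The difference passed the threshold without control replicate 1 (exact p = 0.0231), control replicate 4 (exact p = 0.0475) or sialyllactose replicate 4 (exact p = 0.0448).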

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

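The tests of pigment, vessel, muscle and myelin tissue in control replicate 2 were chosen only after that array's values were seen, and myelin was separated from the other tissues after its test had been run with them. Over 200 groups of 9 values, 15 had 1 array far from the others, where chance gives about 10.

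Control replicate 2 lay at a Euclidean distance of 32.6 from its group mean, where the other control arrays lay between 20.7 and 25.3. Of its tested probe sets, 30.3% were higher or lower than on all other 17 arrays, against 7.20% to 13.4% on each of those. Among genes picked for their distance, LGALS3 was at 3.70 on this array against 2.39 ± 0.40 (SD) on the others, APOE at 5.53 against 4.55 ± 0.42 and MEX3C at 4.04 against 5.38 ± 0.15. The 3' minus 5' difference of the actin and GAPDH control probe sets gave no sign of degraded RNA, at 2.31 on this array and 2.09 to 2.77 on the others. It covers these transcripts only and does not exclude degradation. Pigment epithelium, blood vessels or muscle stay open: 0 of these 3 list scores exceeded those of all other arrays (control replicate 2 ranked 7, 16 and 17 of 18 from the highest), but a score within the range of the others excludes none of them. Myelinated nerve tissue also stays open. The myelin list score of control replicate 2 ranked 4 of 18 from the highest. Of 9 MBP and MOBP probe sets, dim ones included, 3 were highest on this array. The 30.3% above also counts lowest values and covers tested probe sets only, so it gives no base rate for these 3. The largest excess among the 9 was that of an MBP probe set, at 3.61 against at most 2.90. The brightest MBP probe set, at 4.47, lay within 4.24 to 4.61 on the others. No other biological explanation was tested.

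Control replicate 3 had the highest microglia and immune score among controls (0.56 against -0.19 to 0.16), CEBPD at 3.45 against 1.62 to 2.40 and DUSP1 at 6.26 against 5.50 to 5.71. Control replicate 4 had the highest muscle score (0.157 against -0.08 to 0.03). NTRK3 in control replicate 2 was 3.47 against 2.57 to 3.02. In the sialyllactose group, replicate 1 had the highest pigment epithelium score (0.336 against -0.18 to 0.03), the highest antioxidant score (0.0914 against -0.06 to 0.01), VIM at 8.97 against 8.27 to 8.61 and NEU1 at 3.34 against 3.52 to 3.69. Sialyllactose replicate 2 had TMEM263 at 3.03 against 2.73 to 2.86 and OCA2 at 1.30 against 1.65 to 1.97. Sialyllactose replicate 7 had NANS at 5.87 against 5.39 to 5.64 and RPL5 at 8.66 against 8.80 to 8.92, and replicate 4 had PSMB8 at 2.66 against 1.48 to 1.88.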

How the results depend on the processing

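The interferon covariate was chosen after seeing the data. The count of 0 probe sets at an adjusted p under 0.05 held under all 11 other settings and without each of the 18 arrays. Probe sets at an unadjusted p under 0.01 numbered 139 (45 higher, 94 lower) with the 50% filter, which tests fewer probe sets, 304 (176 higher, 128 lower) with no filter, and 178 to 293 when single arrays were left out. Lists passing camera numbered 0 with gene means over probe sets, 0 with estimated correlations, 0 with fry, and 1 to 2 without single arrays; the cause was not tested. The labels do not say whether the replicate numbers pair the piglets. Same-numbered arrays correlated at -0.113 to 0.164, 3 of 9 over 0.1, and 3 of 9 arrays in each diet correlated best with their own number. These values were not tested against chance, so a pairing is neither shown nor excluded. With the replicate number as a block, 0 probe sets passed, 215 had an unadjusted p under 0.01, and 2 lists passed camera with the preset correlation, ribosomal proteins and Mueller glia (adjusted p = 0.0216 for Mueller glia). Without the block, camera with the preset correlation gave them an adjusted p of 0.000195 and 0.201. With an estimated correlation and no block it was 0.722 for both. Diet's share of variance was 6.12% to 6.86% without single arrays and 5.73% to 11.9% in other settings, the highest with the block removed (exact sign-flip permutation p = 0.238). The chance share of 5.88% holds for all 18 arrays without a block. It is higher with fewer arrays or with the block removed, so the larger shares are no sign of a larger diet effect. The spread difference ran from -2.32 to -0.49 without single arrays and was 0.122 with the first principal component removed (exact permutation p = 0.868). Of 2069 values of named genes, 2053 kept their sign, the others being those of NEU1, ST8SIA4 and OPN1SW, and none passed. Leaving out 1 array moved the difference of 24 of the 72 named genes by over 1.5 times: OPN1SW, GNE, NANS, CMAS, NEU1, ST8SIA4, NCAM1, GLUL, RLBP1, CEBPD, ARR3, SNAP25, VAMP2, ST6GAL1, ST3GAL4, GM2A, CADM1, CNGA1, SAG, OCA2, CD14, DUSP1, ELOVL6 and PSMB8. Ribosomal proteins passed in 26 of 29 settings, other lists 3 times in all. Dim probe sets limit what can be seen, since RMA compresses differences near background.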

Other observations

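The tests of the interferon pattern were chosen only after it was seen; those of the ribosomal list and the splits of the arrays were chosen before. Apart from interferon genes, several retinal genes differed strongly between piglets of the same diet. Genes in this paragraph were picked for that spread. SST, a neuropeptide of amacrine cells, ranged from 2.83 to 6.22 in control and from 2.55 to 6.91 with sialyllactose, and ALDH1A1, a retinoic acid synthesising enzyme of the dorsal retina, from 3.97 to 6.97 and from 2.72 to 6.89. CYP26A1, which degrades retinoic acid, had a within-diet SD of 0.679, where the median over all genes was 0.144. TTR, abundant in pigment epithelium, ranged from 4.54 to 8.32 in control, and the activity-dependent genes FOS and EGR1 ranged 9.54-fold and 7.42-fold over all 18 arrays. Of the 50 most variable genes, 3 had a diet difference at an unadjusted p under 0.05, and none passed adjustment.

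Interferon response genes varied together between piglets of both diets. Array quality or normalization stays open: the within-diet SD of the list score, 0.679, lay at percentile 100 of 10000 random lists matched on mean expression (highest 0.105), but the list was picked for that SD, so the comparison excludes nothing. Diet accounted for 0.154% of the score's variance, which says nothing about differences within a diet. More immune cells in some retinas also stay open: 8 immune markers had a median slope of 0.0831 on the interferon score (95% bootstrap interval -0.03 to 0.31), but their median level lay at percentile 8.20 of the tested probe sets, too near the floor to exclude it. That level criterion was added after the slopes were seen. A response to infection or another stimulus in some piglets may also underlie the pattern, a hypothesis that these data cannot test.

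Chance could not be excluded for 2 of the counts between diets. Among 100 splits of the 18 arrays into 9 and 9, the real one included, 14 gave at least the real 219 probe sets at an unadjusted p under 0.01 (highest of the others 454), and 80 gave at least the 1 list that passed camera (highest 5). For the real 0 probe sets at an adjusted p under 0.05 the count of splits, 100, was fixed in advance and tests nothing (highest of the others 3). The ribosomal protein list passed camera with the preset correlation in 44.4% of the 99 other splits, so the real call may reflect genes that vary together. The list's median difference of -0.04 lay at percentile 0 of 10000 random lists matched on mean expression (95% of them between -0.03 and 0.003). Those lists were not matched on correlation, estimated at 0.377 for this list, which camera had already called lower than other genes. Whether a shift of all highly expressed genes contributed therefore stays open.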
